A study of Homo sapiens with 6 samples.

How the data were processed

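RNA from MCF-7 cells transfected with siControl (3 libraries) or siRNF187 (3 libraries) was extracted with Trizol and made into BGISEQ-500 libraries, per the labels' protocols. The siRNA sequence, whether it was one siRNA or a pool, and the time after transfection are not given in the sources used here. The authors deposited one table per library with gene-level FPKM values, per the file headers, rounded to 0.01. GRCh38 is the genome build named in the submitters' processing notes. The aligner, the counting tool, the gene annotation and any filter are not given in the sources used here, and neither is the use of strand. Each table listed the same 17193 genes by Entrez identifier and symbol, nearly all of them protein-coding. The list of mitochondrially encoded genes had 0 members among them and was not analysed here.

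FPKM values carry no read numbers. Low values of genes shorter than 1000 nucleotides were compared between libraries to look for whole-read steps. At the best relative depth, 39.2% to 57.1% of ratios (43 to 64 genes) were small whole ratios within rounding, against a median of 24.5% to 29.8% over other depths, so reads were not recovered and depth is unknown. No counting interval or detection limit is therefore given, and precision comes only from the spread between the 3 libraries of a group. FPKM divides by a sum over genes, so a strong rise of abundant transcripts lowers all others slightly, and differences in annotation length change levels between genes but not the comparison of one gene between groups.

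Groups were taken from the sample titles. Identical values made up 0.11% to 0.51% of genes between any 2 libraries, so no library was treated as a repeat of another. The main test was limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3 on log2(FPKM + 1), over 11008 genes with a mean of at least 1 FPKM across the 6 libraries. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fixed plan named a count test should the files hold counts. They hold FPKM, so the test planned for normalized values was used, and edgeR and DESeq2 were not used. Replicate numbers were not used as a block in the main test.

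There were 33 gene lists with 992 symbols, written before the data were examined, of which 951 symbols matched a listed gene, 23 of them through another symbol in the RefSeq table. Lists with at least 5 tested members (31 lists) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, with adjustment over lists. Members were also counted by the gene test and when adjusted over the list alone. The named genes followed a rule fixed before the data were examined. They were RNF187, TP53, MDM2, MDM4, CDKN1A and ESR1, then the 12 highest and 12 lowest log2 fold changes among genes with an adjusted p under 0.05, a standard gene symbol, a mean above the median of tested genes (11.0 FPKM) and no overlap between groups. One gene that the rule names is not reported here. In each list described, up to 4 members with the smallest p were added. Genes named outside the rule were chosen after their values were seen. These are the few members going against their list, BCL2, the further p53 targets, MCM6, UHRF1 and the MTRNR2L genes.

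The procedure was tested on simulated data, with normal noise of the measured spread and 200 of 11008 genes changed. It recovered 40.3% of changes of 0.5 log2, 88.1% of changes of 1 and 100% of changes of 2, with 5 false calls (3.18% of calls). A p53 list raised by 1 was called by camera at the preset and at the estimated correlation, and at the preset correlation 0 of 30 other lists were. The noise was drawn for each gene on its own, without correlation between genes. In the data the estimated correlation of the p53 list was 0.17, so the simulation does not test the list calls under such correlation. Nor does it test them with as many changed genes as the data hold.

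Alternatives were a replicate block, no filter and a stricter filter (mean of at least 5), each library left out, TMM-like scaling, quantile normalization, pseudocounts of 0.1 and 0.5, no trend, a fold threshold of 1 log2, an adjusted p of 0.01 and the other set tests. Scaling to an FPKM sum of 1000000 and leaving out genes with a sequence motif were added after seeing the data. Gene coordinates and transcripts came from GENCODE 29 on GRCh38, to which 10743 of the 11008 tested genes were matched. For the sequence search, the longest annotated 3' UTR of at least 50 nucleotides was taken for 10617 genes. It may not be the 3' UTR that MCF-7 cells use, which gene-level FPKM values do not show. The log2 fold change was regressed on the presence of each of 15717 7-mers found in at least 100 genes, with UTR length, GC content and siControl expression as covariates and Bonferroni adjustment. The search recovered a 7-mer planted in shuffled fold changes, with an effect larger than the largest fall found in the data. Shuffling removes any likeness between related genes, so this does not test whether the p-values of the search are well calibrated. For the follow-up with an 8-mer, coding length was added as a covariate. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.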

Results

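Messenger RNA levels were measured in MCF-7, an estrogen receptor positive line of luminal breast cancer that carries wild-type TP53. The cells received a small interfering RNA (siRNA), a short double-stranded RNA that directs the degradation of transcripts matching it. One group of 3 libraries received a control siRNA (siControl) and the other group of 3 received an siRNA against RNF187 (siRNF187). RNF187 is a RING-type E3 ubiquitin ligase, also described as a coactivator of the AP-1 transcription factor, and the series concerns its part in regulating p53 signalling in breast cancer. The deposited values are FPKM (fragments per kilobase of transcript per 1000000 fragments) for 17193 genes, of which 21 were at 0 in every library. FPKM sums were 602666, 575057 and 624601 in the siControl libraries and 645118, 618886 and 594696 in the siRNF187 libraries. The number of reads per library is unknown, so no counting interval is given. Pearson correlations of log2(FPKM + 1) across genes, which are not independent replicates, were 0.987 to 0.996 between libraries of one group and 0.928 to 0.947 between libraries of different groups. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

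The first comparison asked whether RNF187 itself was lower in the siRNF187 libraries. RNF187 (Entrez 149603; GRCh38, chromosome 1, 228487061 to 228495766, plus strand, protein-coding) stood at 47.24, 44.32 and 50.04 FPKM in the siControl libraries and at 5.78, 7.39 and 4.85 FPKM in the siRNF187 libraries. The mean went from 47.2 ± 2.86 to 6.01 ± 1.29 FPKM (SD, n = 3 each), which is 87.3% lower. RNF187 fell by 2.80 ± 0.13 (SE) on the log2(FPKM + 1) scale, with an adjusted p of 2.16e-07 in limma. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow. Fold changes below are on this log2(FPKM + 1) scale, which understates the change of genes with low FPKM.

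The p53 axis moved at the mRNA level downstream of TP53 far more than at TP53. CDKN1A (GRCh38, chromosome 6, 36676460 to 36687339), which encodes the cyclin-dependent kinase inhibitor p21, went from 70.6 ± 4.81 to 7400 ± 622 FPKM, a log2 change of 6.69 ± 0.09 (SE; limma adjusted p = 5.07e-10). It then made up 1.19% of the siRNF187 FPKM sum. MDM2 (GRCh38, chromosome 12, 68808176 to 68850686), the ubiquitin ligase that degrades p53, went from 12.2 ± 0.92 to 253 ± 21.8 FPKM (log2 change 4.26; adjusted p = 5.22e-09). Its relative MDM4, an inhibitor of p53, rose from 3.10 ± 0.24 to 7.51 ± 0.76 FPKM (log2 change 1.05; adjusted p = 2.61e-05). TP53 mRNA fell by 0.27 on the log2 scale, from 48.3 ± 1.80 to 40.0 ± 1.41 FPKM (adjusted p = 0.00693). That call was lost with TMM-like scaling of the libraries, where the log2 change was -0.16 (adjusted p = 0.137). ESR1, the gene of estrogen receptor alpha, fell by 0.93, from 60.5 ± 13.4 to 31.0 ± 2.98 FPKM (adjusted p = 4.58e-04).

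**Figure D1:**
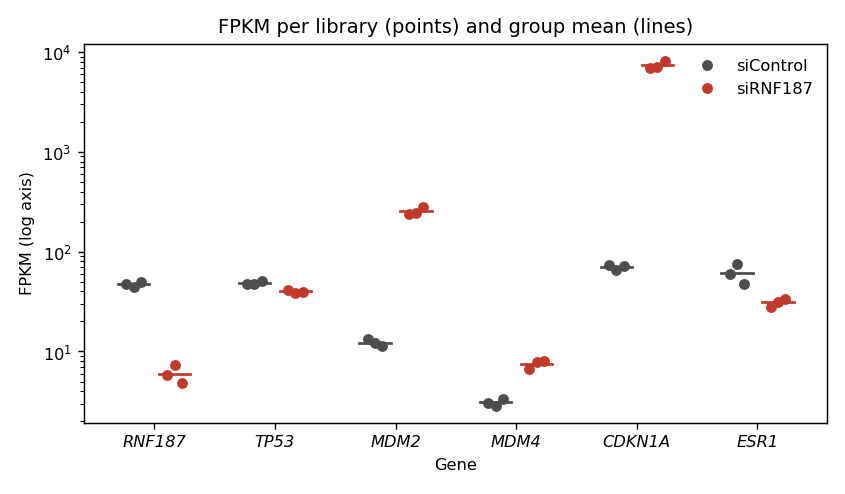
FPKM on a log axis in each siControl (grey) and siRNF187 (red) library for RNF187, TP53, MDM2, MDM4, CDKN1A and ESR1, with points for the 3 libraries of a group and lines for their mean. RNF187 lies at 44.32 to 50.04 FPKM in the siControl libraries and at 4.85 to 7.39 in the siRNF187 libraries, while CDKN1A goes from a mean of 70.6 to a mean of 7400.

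The second comparison asked which genes differed between siRNF187 and siControl cells. Among the genes with the highest fold changes under the naming rule were CDKN1A, then FOSL1 (5.29), an AP-1 subunit, ACTA2 (4.98), the smooth muscle actin, and GDF15 (4.37), a secreted stress cytokine. MDM2, BBC3 (4.07), FAS (3.97), LIF (3.82), TP53I3 (3.73), GADD45A (3.60) and TMEM40 (3.52) followed. ACTA2 (GRCh38, chromosome 10, 88935074 to 88991339, minus strand) overlaps FAS (88990582 to 89015785, plus strand). The use of strand is unknown, so shared reads between ACTA2 and FAS cannot be excluded. FAS, LIF and FOSL1 started from means of 0.92, 0.64 and 0.90 FPKM and reached 29.04 ± 0.75, 22.2 ± 1.49 and 72.7 ± 4.10 FPKM. GDF15 went from 148 ± 10.8 to 3085 ± 268 FPKM. Under the same rule, the strongest fall on the log2(FPKM + 1) scale was that of ASB13, a substrate-binding subunit of a cullin ubiquitin ligase. ASB13 fell by 3.72 from 26.1 ± 0.25 to 1.08 ± 0.39 FPKM. MCM3, a subunit of the replicative helicase, fell by 3.56 from 71.0 ± 0.96 to 5.09 ± 0.27 FPKM. ARMT1 fell by 3.24 and TOMM40, the import channel of the mitochondrial outer membrane, fell by 2.91 from 234 ± 19.3 to 30.4 ± 5.21 FPKM. IMPDH1, an enzyme of guanine nucleotide synthesis, fell by 2.89. RNF187 and 6 other genes complete the 12 lowest: KIF23 (-2.94), HJURP (-2.92), ASF1B (-2.82), KIF20A (-2.77), CEP55 (-2.71) and TARP (-2.71). TARP lies within the T-cell receptor gamma locus, where overlapping genes can share reads, so its value is uncertain. The sequence TCAGGTC, whose presence in 3' UTRs went with lower fold changes across genes (difference -0.24 log2, z = -9.72), lies, among the lowest genes, in the 3' UTRs of ASB13, ARMT1, IMPDH1 and RNF187. MCM3 and TOMM40 hold it in the coding sequence and not in the 3' UTR, which that difference does not cover. Named genes that rose hold it in the 3' UTR too, namely MDM4, NUPR1 (2.27), IER5 (2.05), FOSL2 (0.94) and TKT (0.89). For every gene the longest annotated 3' UTR was searched, 4975 nucleotides for NUPR1. Whether the cells express that form is unknown, for genes that fell and for genes that rose.

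Of the 11008 genes tested, 6674 (60.6%) had an adjusted p under 0.05 in limma, 2675 of them higher and 3999 lower in siRNF187 cells. At least 1 log2 unit of change was reached by 469 genes that rose and 765 that fell. The 3 values of one group did not overlap those of the other for 7258 genes (65.9%), against 10% by chance. The median log2 change of all tested genes was -0.10, and TMM-like scaling and quantile normalization moved it by 0.10 and 0.11. The share of changed genes that rose was 40.1% as deposited, 49.8% with TMM-like scaling, 49.9% after quantile normalization and 36.8% with each library scaled to the same FPKM sum, where the median moved by -0.04. Small changes are to be read relative to that shift.

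**Figure D2:**
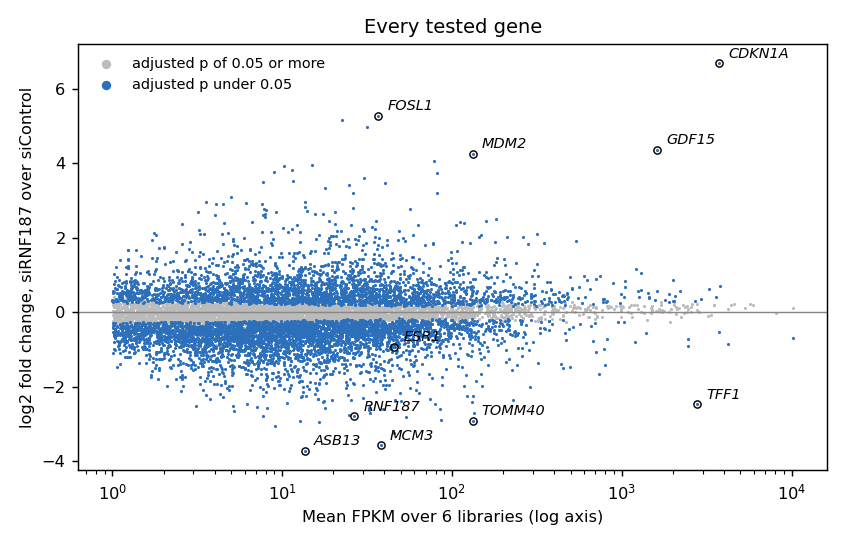
The log2 fold change of each of the 11008 tested genes, siRNF187 over siControl, against its mean FPKM over the 6 libraries (log axis), with blue points for an adjusted p under 0.05 and circles around 10 named genes. CDKN1A stands highest at 6.69, and ASB13, MCM3, TOMM40 and RNF187 lie between -3.72 and -2.80.

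The third comparison concerned the p53 pathway named in the series title, through a list of direct p53 target genes. Of its 60 tested members, 55 rose and 1 fell, with the same counts when adjusted over the list alone, and the median log2 change was 1.92. The risers covered several known branches of the p53 response. Cell cycle arrest was represented by CDKN1A, BTG2 (2.79) and GADD45A. Apoptosis was represented by BBC3, which encodes PUMA and went from 7.89 ± 0.30 to 149 ± 19.7 FPKM, by FAS and by BAX (2.04). DNA repair and nucleotide supply were represented by XPC (2.70), DDB2 (2.40) and RRM2B (2.34), and feedback on p53 by MDM2 and PPM1D (2.34). TSKU was the member that fell, by 2.25. The members CCNG2 (-0.30), PMAIP1 (0.22), KITLG (0.07) and TOB1 (0.00) did not pass the test. These members, like those in the previous sentences other than CDKN1A, MDM2, GDF15, FAS, BBC3, BAX and GADD45A, were chosen after their values were seen. Limma's camera test with a preset correlation of 0.01 between genes placed the list above other genes (adjusted p = 2.08e-28). That call was lost with an estimated correlation, where the adjusted p was 0.249.

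**Figure D3:**
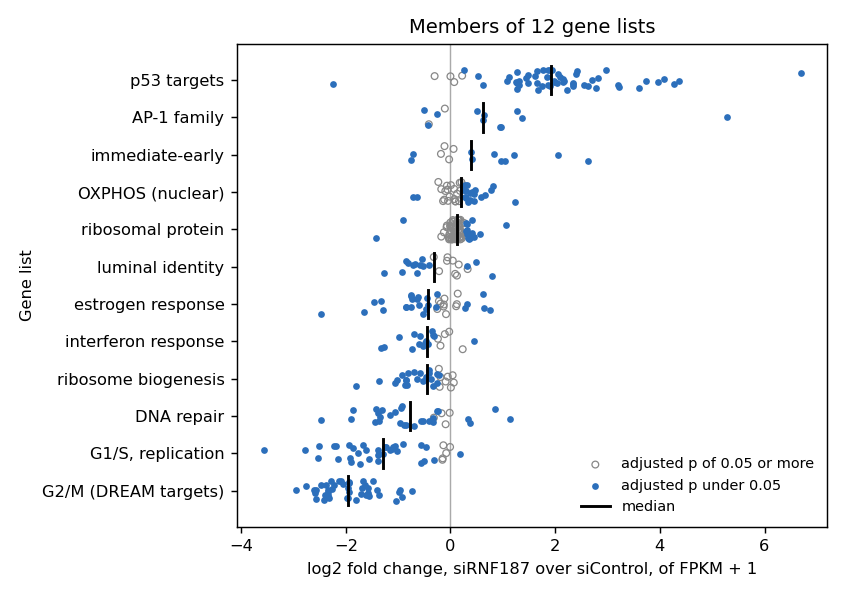
Log2 fold changes of FPKM + 1, siRNF187 over siControl, for the tested members of 12 gene lists, each point a gene (blue for an adjusted p under 0.05, open grey otherwise) and each black bar the list's median. The median is 1.92 for the p53 targets and -1.97 for the G2/M list.

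The remaining lists were compared next, starting with the cell cycle. All 43 tested genes of the G2/M list, which holds mitotic genes repressed by the DREAM complex, fell, with a median of -1.97. PLK1, a mitotic kinase, fell by 2.41 from 220 ± 8.84 to 40.6 ± 0.99 FPKM, and CCNB1 (cyclin B1) fell by 2.61 from 147 ± 3.74 to 23.4 ± 1.81 FPKM. AURKA fell by 2.32 and CDC20, the activator of the anaphase-promoting complex, fell by 2.47. Camera gave the list an adjusted p of 9.35e-20, and adjusted p = 0.249 with an estimated correlation. Of 39 G1/S and replication genes, 33 fell and 1 rose, with a median of -1.29. Beside MCM3, the flap endonuclease FEN1 fell by 2.18, the uracil glycosylase UNG by 2.16 and the helicase subunit MCM7 by 1.55, while LIG1 rose by 0.19. The camera adjusted p of this list was 2.24e-11, and the adjusted p was 0.249 with an estimated correlation. Histone genes went the other way, with 7 of 13 tested members higher, none lower and a median of 0.54. Among them were H2BC5 (0.92), H4C14 (1.08), H1-2 (0.81) and H1-3 (1.21, from a mean of 0.31 to 2.09 FPKM). Of 32 histone genes on the list only 15 were among the deposited genes. The tested members therefore do not speak for replication histones as a whole. For these histone genes the camera adjusted p was 0.0166, against an adjusted p of 0.401 with an estimated correlation. The histone call was lost among genes with a mean FPKM of at least 5 (adjusted p = 0.119).

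DNA repair genes mostly fell, with 24 of 32 lower, 4 higher and a median of -0.77. EXO1, a mismatch repair exonuclease, fell by 2.47, MSH6 by 1.91 and PARP1 by 1.35, while RAD51C rose by 1.14 and ERCC1, ERCC2 and ERCC5 rose by 0.85, 0.38 and 0.33. Camera's adjusted p was 3.58e-04, and the adjusted p was 0.286 with an estimated correlation. Among 30 ribosome biogenesis genes, 22 fell (23 when adjusted over the list alone) and none rose, with a median of -0.45. BYSL, needed for the small ribosomal subunit, fell by 1.80 from 26.4 ± 1.77 to 6.89 ± 0.60 FPKM, NOP2 by 1.37, PNO1 by 1.07 and UTP4 by 0.84. For this list the camera adjusted p was 3.58e-04 and the adjusted p was 0.447 with an estimated correlation. Of the 77 ribosomal protein genes, 62 did not pass the test, 13 rose and 2 fell (6 and 2 when adjusted over the list alone). RPL11, a ribosomal protein that binds MDM2, rose by 1.06 and RPL3 by 0.57, while RPL4 fell by 1.42 and RPS17 by 0.91. The median of the ribosomal protein list was 0.13 (camera adjusted p = 0.00536) and turned to -0.02 after quantile normalization. With an estimated correlation the adjusted p was 0.798. Its call was also lost without siControl replicate 2 (adjusted p = 0.128) and without siRNF187 replicate 1 (adjusted p = 0.109).

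AP-1 was of interest because RNF187 is known as a coactivator of c-Jun. Of 13 AP-1 family genes, 8 rose and 3 fell, with a median of 0.63. Besides FOSL1, JUND rose by 1.27 from 118 ± 6.57 to 290 ± 47.0 FPKM, ATF3 by 1.37 and FOSL2 by 0.94, whereas JDP2, MAFK and MAFG fell by 0.50, 0.43 and 0.25. Camera's adjusted p was 0.0335, and the adjusted p was 0.547 with an estimated correlation. The call was also lost among genes with a mean of at least 5 FPKM (adjusted p = 0.0911). Known AP-1 target genes were not called as a list (11 tested, 4 higher, 1 lower, camera adjusted p = 0.205): SERPINE1 rose by 2.38, AREG by 0.64 and EZR by 0.56, and CCND1 (cyclin D1) fell by 1.02. Immediate-early genes rose in 8 of 14 cases and fell in 2, SRF and EGR3, with a median of 0.40. EGR1 rose by 2.62 from 1.41 ± 0.15 to 14.1 ± 3.47 FPKM, IER5 by 2.05, IER2 by 1.22 and IER3 by 0.83. The camera adjusted p was 0.0215 for this list and the adjusted p was 0.547 with an estimated correlation. Adhesion and matrix genes rose in 9 of 23 cases and fell in 3. The integrin ITGA3 rose by 1.67 and the syndecans SDC1 and SDC4 by 1.16 and 1.07, while ITGB5, TLN1 and ITGA2 fell by 0.84, 0.97 and 1.29. Their camera adjusted p was 0.0335, against an adjusted p of 0.547 with an estimated correlation. This call was lost in 6 alternatives, among them leaving out siControl replicate 3 (adjusted p = 0.0963), siRNF187 replicate 2 (adjusted p = 0.0602) or siRNF187 replicate 3 (adjusted p = 0.0777).

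Estrogen response genes fell in 20 of 35 cases and rose in 5, with a median of -0.44. TFF1, a secreted peptide under direct control of the estrogen receptor, fell by 2.48 from 4711 ± 656 to 851 ± 157 FPKM. XBP1 fell by 1.64, OLFM1 by 1.29 and the zinc transporter SLC39A6 by 1.33, while CTSD, CISH, AREG, HSPB8 and RAPGEFL1 rose by 0.62, 0.76, 0.64, 0.31 and 0.28. Camera gave an adjusted p of 0.0431, and adjusted p = 0.547 with an estimated correlation. The call was lost in 4 alternatives, among them leaving out siRNF187 replicate 1 (adjusted p = 0.0533) or siRNF187 replicate 2 (adjusted p = 0.0602). Of 23 luminal identity genes, 11 fell and 3 rose, and the list was not called (median -0.32, camera adjusted p = 0.336). AGR2 fell by 1.27, the keratin KRT18 by 0.86 and SPDEF by 0.82, while ELF3, MUC1 and GATA3 rose by 0.48, 0.79 and 0.31. Only 5 of 26 basal or mesenchymal markers reached the filter. ACTA2 rose, and LOX and COL1A1 fell by 1.21 and 0.40. VIM had a log2 change of 0.38 (limma adjusted p = 0.0706) from 0.91 ± 0.24 FPKM in siControl cells. The span of ACTA2 overlaps that of FAS, so the rise of ACTA2 is weak evidence of a mesenchymal trait. Of 20 leukocyte, endothelial and blood markers, 2 reached the filter, HBA1, which fell by 0.56, and CD68 at 2.59 ± 0.14 and 2.72 ± 0.20 FPKM (adjusted p = 0.648).

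Interferon response genes, a known readout of transfected double-stranded RNA, fell in 14 of 20 cases and rose in 1 (BST2, by 0.45), with a median of -0.46. ISG20 fell by 1.33, OAS3 by 1.27, USP18 by 0.97 and EIF2AK2 by 0.57. The camera adjusted p was 0.0250 and the adjusted p was 0.286 with an estimated correlation. The call was lost in 4 alternatives, among them leaving out siControl replicate 3 (adjusted p = 0.0615) and testing genes with a mean of at least 5 FPKM (adjusted p = 0.270). Heat shock genes were lower in 9 of 15 cases, with HSPA1A, HSPH1, HSPA1B and HSPA8 falling by 1.40, 1.32, 1.13 and 0.99, and HSPD1 rising by 0.30, although the list missed the threshold (camera adjusted p = 0.0549). It passed in 5 alternatives, one of which left out siRNF187 replicate 3 (adjusted p = 0.0423). Autophagy and lysosome genes rose in 18 of 31 cases and fell in 5, with a median of 0.29. BECN1 rose by 0.87 and GABARAPL2 by 0.68, whereas MAP1LC3B fell by 0.97 and ATG9A by 0.81. Their camera adjusted p was 0.00888, against an adjusted p of 0.547 with an estimated correlation. Nuclear genes of oxidative phosphorylation rose in 19 of 41 cases (18 when adjusted over the list alone) and fell in 2, ATP5F1B and NDUFV2, with a median of 0.21. NDUFS2 of complex I rose by 1.24, SDHB of complex II by 0.81, ATP5PB by 0.77 and NDUFB5 by 0.66. Camera gave an adjusted p of 0.00180, and adjusted p = 0.547 with an estimated correlation.

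Apoptosis regulators of the BCL2 family split, with 7 of 17 higher and 6 lower. BBC3, BAX, BCL2L1 (1.99) and BAK1 (0.67) rose, and BCL2, the survival factor, fell by 1.33, and the list was not called (camera adjusted p = 0.211). Among 19 death receptor and caspase genes, 9 rose and 4 fell. FAS, TNFRSF10B (2.23), which encodes a receptor for the ligand TRAIL, and TRADD (1.05) rose and CASP2 fell by 0.95. The list's camera adjusted p of 0.0549 came under the threshold in 4 alternatives, of which 2 left out siControl replicate 2 (adjusted p = 0.0448) or siRNF187 replicate 1 (adjusted p = 0.0441). Genes of the ATF4 and amino acid response were 8 higher and 8 lower of 25 (camera adjusted p = 0.236), led by SESN2 (2.81), which is also on the p53 list, NUPR1 (2.27), DDIT4 (1.92) and DDIT3 (1.25). The median of that list, -0.01, and its mean, 0.28, differed in sign. NRF2 and oxidative stress genes were 8 higher and 2 lower of 20 (camera adjusted p = 0.109), with HMOX1 rising by 1.86, TKT by 0.89, SOD1 by 0.41 and PRDX1 by 0.35. Regulators of p53 were 4 higher and 9 lower of 23 (camera adjusted p = 0.874). PPP1R13L, an inhibitor of p53, rose by 1.24 beside MDM4, and the checkpoint kinases CHEK1 and CHEK2 fell by 1.78 and 0.73.

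In all, 14 of 31 lists passed camera's threshold, 8 of them upward and 6 downward. With an estimated correlation camera passed 0 lists, with a smallest adjusted p of 0.249, and 5 lists had an unadjusted p under 0.05: p53 targets, G2/M, G1/S and replication, DNA repair and interferon response. Fry, which asks whether a list's genes move on balance one way and does not compare them with other genes, passed 23 lists.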

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

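Scaling to an FPKM sum of 1000000 and removal of genes with the motif described below were chosen after seeing the data. All alternatives with a replicate, filter, scaling, pseudocount or trend change, and the adjusted p of 0.01, gave counts of changed genes within 1.5 times of 6674. Leaving out 1 library gave 5516 to 7182. Without the 1519 motif genes, 5613 of 9489 genes changed. With a fold threshold of 1 log2 the counts were 1234 changed, 469 higher and 765 lower, by construction of the threshold. The TMM-like and quantile fits shared 5970 and 6005 calls with the main test, all in the same direction. Deviations of same-numbered libraries from their group mean correlated at 0.25, -0.05 and -0.44, so replicate number did not go with a common deviation. Between differently numbered libraries of different groups they ranged from -0.47 (siControl 2 with siRNF187 1) to 0.49 (siControl 2 with siRNF187 3). Part of the spread within groups thus ran in a direction common to both groups, and its source was not tested. These values cannot show whether the samples were paired. The replicate block gave 6165 changed genes, 6112 of them shared with the main test. RNF187 passed in every fit that tested it, at -2.93 to -2.67 when 1 library was left out. The p53 list kept its camera call in every alternative but one, the estimated correlation (median 1.92, adjusted p = 0.249), and its adjusted p was at most 4.91e-24 elsewhere in camera and 3.65e-05 in fry. The estimated correlation also took the 14 called lists to 0. A correlation above the preset 0.01 cannot be the whole cause. For the interferon list the estimate was -0.04, yet camera's unadjusted p went from 0.00887 to 0.0462. What else differs between these forms of camera was not tested. Camera's direction turned for 4 lists, of which 3 were never called. For NF-kB genes this was with no filter (median -0.027), a mean of at least 5 (-0.16), TMM-like scaling (0.0342), a fixed FPKM sum (-0.14), without siControl replicate 2 and without siRNF187 replicate 3 (-0.17 to 0.10 over all left-out libraries). For p53 regulators it was with a mean of at least 5 (-0.19) and without siRNF187 replicate 1 (-0.235 to -0.072 over left-out libraries). For ubiquitin and proteasome genes it was after quantile normalization (-0.0378) and without siRNF187 replicate 1 (-0.0386 to 0.0335 over left-out libraries). The ribosomal protein list turned after quantile normalization (-0.0199), and the cause was not tested. For single named genes, 2111 values kept their direction and side of the threshold, 2 lost it (TP53 with TMM-like scaling, COL1A1 after quantile normalization) and 3, all for VIM, gained it. For the lists, over 16 refits with camera at its preset correlation, 455 values kept both, 18 lost the call in the same direction, 10 gained it and 11 turned direction, the ribosomal protein value among these also losing its call (adjusted p = 0.948). Alternatives planned for counts (other size factors, a second count test) were not run because the values are FPKM. Without read numbers, the uncertainty of genes near 1 FPKM cannot be split into counting error and other spread.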

Other observations

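Several groups outside the called lists also held strong single changes. Of 13 genes of the small RNA machinery, 6 fell and none rose, among them DICER1 by 1.19, DGCR8 by 1.01, AGO2 by 0.90 and XPO5 by 0.89 (camera adjusted p = 0.128). Hypoxia and glycolysis genes were lower in 13 of 30 cases and higher in 1, PFKL, which rose by 1.21, while LDHA fell by 0.78, EGLN1 by 0.86 and PFKFB4 by 0.68. That list was not called as deposited (camera adjusted p = 0.153) and passed after quantile normalization (adjusted p = 0.0251). Cholesterol synthesis genes split 7 up and 8 down of 23, with HSD17B7 rising by 0.98, PMVK rising by 0.76, SQLE falling by 1.25 and DHCR7 falling by 0.78 (adjusted p = 0.690). In fatty acid synthesis, ME1 rose by 0.96 and ACACA by 0.57, and ELOVL6 fell by 1.01 and SCD by 0.75 (3 up and 4 down of 14, adjusted p = 0.690). In the unfolded protein response, XBP1 fell by 1.64 and SDF2L1 by 0.82 while CALR rose by 0.94 and CRELD2 by 0.55 (6 up and 4 down of 24, adjusted p = 0.357). Proteasome and ubiquitin genes split 8 and 8 of 34 (PSMC3 0.89, UBC 0.69, PSMA6 -0.54, UCHL5 -0.80; adjusted p = 0.690), and genes of the YAP and Hippo pathway were 6 up and 4 down of 14 (YAP1 0.67, FJX1 -1.60, AJUBA -0.95, TEAD4 -0.73; adjusted p = 0.690). NF-kB genes were 2 up and 5 down of 13, with TNFAIP2 falling by 1.18, NFKB1 by 0.93 and ICAM1 by 0.70 and BCL3 rising by 0.90 (adjusted p = 0.950). The NF-kB median of -0.03 and the cholesterol median of -0.12 went against camera's upward direction, which is relative to other genes. The means of the unfolded protein (-0.01), proteasome (-0.02), fatty acid (-0.04) and YAP (-0.09) lists were below 0 while their medians were above 0.

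Gene families grouped by symbol were looked at after the data were seen, 72 in all. ZNF genes, which encode zinc finger proteins, were 137 higher and 42 lower of 313 tested, with a median of 0.19 (camera adjusted p = 3.89e-05, adjusted p = 0.999 with an estimated correlation). NUP genes, which encode nuclear pore proteins, were 18 lower and 1 higher of 23, with a median of -0.47 (camera adjusted p = 0.0284, adjusted p = 0.999 with an estimated correlation). MTRNR2L2 and MTRNR2L8, nuclear copies that resemble the mitochondrial 16S ribosomal RNA, rose from 2881 ± 86.0 to 4705 ± 188 FPKM and from 1419 ± 42.2 to 2603 ± 94.3 FPKM (limma adjusted p = 2.09e-04 and 2.36e-05). Reads from the mitochondrial transcript can be assigned to such copies, so their values are uncertain.

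For the patterns weighed here, the tests of the interferon list, of scaling and of the MCM genes were chosen after the results they measure were seen, as were the 8-mer follow-up and the fit without motif genes. The splits, the gain of the top genes and the 7-mer search were written before theirs.

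The first pattern is the fall of MCM3 beyond the other MCM2-7 genes, a comparison chosen after its value was seen. MCM3 fell by 3.56, which put it 1.65 ± 0.12 (SE) log2 units below MCM6, the lowest of those others. A shared fall of the MCM2-7 genes therefore does not account for all of it. On the log2(FPKM + 1) scale MCM3 also lay 0.78 ± 0.17 below UHRF1, the next lowest of the whole G1/S and replication list. UHRF1 went from a mean of 14.2 to 1.20 FPKM, where this scale understates the fall. MCM3 is thus not set apart from that whole list. A search of 3' UTRs put the 7-mer TCAGGTC first among 15717 on the negative side (808 genes, difference -0.24 log2, z = -9.72), followed by CAGGTCA (z = -9.30), while the leading 7-mer on the positive side, CGGAGAA, had z = 6.18. In this regression across genes, which are not independent replicates, the Bonferroni-adjusted p of TCAGGTC was 4.10e-18. On the negative side 8 of the 7-mers had such a p under 0.05, and on the positive side 4 did. Passing that threshold alone therefore does not mark a seed match. The leading pair joins to the 8-mer TCAGGTCA. RNF187 holds this 8-mer in its coding sequence (GRCh38, chromosome 1, 228493201 to 228493208, exon 3 of 4, plus strand). RNF187 also holds the 7-mer TCAGGTC in its 3' UTR. The values are compatible with an siRNA whose seed pairs with either site, with partial matches lowering other transcripts. They do not locate the site that the siRNA targets. The siRNA sequence was not used here, and 15.1% of the 7-mers occur in RNF187 transcripts, so the presence there is weak evidence by itself.

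Genes with TCAGGTCA in the 3' UTR (297 genes) had a median log2 change of -0.34, against -0.10 for 10099 genes without it, and 12.8% of them fell by at least 1 log2, against 6.79%. The 8-mer was chosen from these same 3' UTRs and fold changes, so those values describe the pattern and do not test it again. Coding sequences were not part of the search. In 221 genes with the 8-mer only in the coding sequence the adjusted difference was -0.19 ± 0.04 (SE, z = -4.41), and 0 of 275 other orderings of the same bases were as low (lowest z = -2.79). These 221 genes include the target RNF187, and MCM3 and TOMM40, which had already been seen to fall. Genes holding only a leading 7-mer in the 3' UTR, such as RNF187, were not left out. The value is therefore not a fully separate test, and a fit without these genes was not run. ASB13 and ARMT1 hold the 8-mer in the 3' UTR, and MCM3 and TOMM40 hold it in the coding sequence. Among other named genes, BYSL, NOP2, RPS17, TNFAIP2 and AJUBA hold it in the 3' UTR, and NFKB1 in the coding sequence. All of these fell. MDM4 holds it in its 3' UTR and rose. Each 3' UTR here is the longest annotated one, 1467 nucleotides for RPS17 and 9419 for MDM4, and may not be the expressed one. IMPDH1, which holds the 7-mer TCAGGTC, and KIF23, HJURP, ASF1B, KIF20A and CEP55, also among the lowest genes, have no copy of the 8-mer in the parts searched, and 3' UTR holders made up 5.09% of the 747 searched genes that fell by at least 1 log2.

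The second pattern is the rise of the p53 targets. An innate response stronger to siRNF187 than to siControl would raise interferon genes, but 1 of 20 tested rose and 14 fell. Both groups received siRNA, so a response common to both would not show. The camera call of the interferon list was also lost in 4 alternatives. Scaling between libraries is argued against by a p53 list median of 2.02 after quantile normalization. A hypothesis that stays open is that the p53 response may follow in part from a transcript other than RNF187 that the siRNA lowers: BYSL and NOP2, which act in ribosome assembly, hold the 8-mer and fell by 1.80 and 1.37, and disturbed ribosome assembly is a known trigger of p53. Genes without the site fell as well: PNO1 and UTP4 lack the 8-mer and fell by 1.07 and 0.84, and without genes holding either leading 7-mer in the 3' UTR 17 of 23 ribosome biogenesis genes fell and none rose (median -0.48, camera adjusted p = 0.00117, adjusted p = 0.488 with an estimated correlation). A second siRNA or a rescue with resistant RNF187 would separate these, and neither was analysed here.

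The third pattern is that more genes fell than rose. After quantile normalization 49.9% of the changed genes rose, but that step centres the fold changes (their median moved by 0.11), so a scaling difference and a true excess of falls cannot be told apart by it, and scaling each library to the same FPKM sum gave 36.8%, a larger excess of falls. A few genes taking up the FPKM sum would not account for all of the shift if that sum were fixed. The 10 genes with the largest gain took 3.11% of the siRNF187 sum, less than the 6.95% needed to move the rest by the median change. The sum was not fixed, at 575057 to 624601 in siControl and 594696 to 645118 in siRNF187 libraries. This comparison therefore does not decide whether those genes account for any of the shift. Because FPKM is divided by transcript length, their share of the reads is unknown. A global change in RNA content per cell stays open, since FPKM cannot show one.

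The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 of the 10 with the highest result in each comparison. It gave 6674 changed genes, 56 changed p53 targets and 14 called lists, and the highest of the other splits gave 0, 0 and 13. At an unadjusted p under 0.05 the mixed splits had 7 to 393 genes in limma, against 7160 in the real split. At the preset correlation, the mixed splits called 8 to 13 lists with 0 changed genes in limma. Each mixed split holds libraries of both groups on both sides. Part of the difference between the groups therefore stays in the comparison, and the rest widens the spread. For this reason the mixed splits do not show what arises by chance, for genes or for lists, and no conclusion is drawn from them.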
